A study of Mus musculus with 4 samples.

How the data were processed

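Total RNA of 4 mouse samples was measured on miRNA arrays with 1 colour: villus epithelial cells and crypt epithelial cells of the small intestine, and organoids grown from small intestinal crypts on day 1 and on day 5 of culture. Each group had 1 array, so there were no replicates, no p-value was computed, and every comparison describes these 4 arrays. Per the labels' protocols, RNA was extracted with a miRNeasy kit and labelled with Cy5 using the miRCURY LNA labelling kit. The array's maker, the scanner and the image software are not given in the sources used here.

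Each deposited scanner table gives, per the file headers, the median intensity of each spot on a linear scale, combined from scans at several gains by straight-line fits, with a second column named as the background median. An array held 3200 spots: 1900 miRNA probes with 1 spot each, 896 blank spots, 16 Spike Control spots and other control probes. The deposited table of processed values was set against the scanner values of the same arrays. Its values are intensities on a linear scale: each column is a straight-line function of that array's spot medians, with its zero at the trimmed mean of the blank spots, a median of 25.0, a largest residual of 0.0536, and no entry where a probe was not above the blank spots. The tool the authors used to make it is not given in the sources used here, and its direction and scale are those of the scanner intensities.

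Intensities were corrected with normexp at an offset of 50 (limma 3.58.1 in R 4.3.3), put on the log2 scale and quantile normalized over the miRNA probes of the 4 arrays. The design written before the data were examined called for normexp on the local background where the tables give it, and on the spot intensity alone otherwise. The column named as background followed the brightness of its own spot: over miRNA probes, the correlation of the log2 values was 0.963 on the villus, 0.961 on the crypt, 0.931 on the day 1 and 0.957 on the day 5 array. On spots above an intensity of 1000 its median was 56.4%, 41.6%, 43.6% and 40.6% of the spot in the same order, and it exceeded the spot for 3.47%, 2.26%, 0.684% and 1.74% of miRNA probes. It was therefore not used as a background, and normexp was run on the spot intensity alone. That choice was made after values had been seen, and the fit with the column subtracted is given as an alternative, under which several results change direction.

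A miRNA was called detected where its intensity exceeded the mean plus 2 SD of the blank spots of its array, after leaving out the highest and lowest 5% of them. The quality marks of the tables were used only to leave out 3 miRNA probes, miR-669h-5p, miR-7000-5p and miR-664-5p, which left 1897. Of these, 12 carry more than 1 miRNA name, such as the probe shared by miR-199a-3p and miR-199b-3p, and their values cannot be assigned to either. A difference was taken as measured where both arrays detected the miRNA. Where only 1 array did, the difference is a lower bound on its size, against the higher of the dim probe's own level and the lowest level among detected probes of that array. Such a bound applies to the setting it was computed in, and other settings can give a smaller one. Probes were compared only with themselves across arrays.

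The 6 pairs of arrays were compared by the number of miRNAs at least 2-fold higher or lower and by the SD of log2 differences over miRNAs detected on both arrays. The day 5 minus day 1 differences were set against the villus minus crypt differences, which share no array, across the miRNAs detected on all 4. Before the data were examined, 22 lists of miRNAs were fixed: miR-192, miR-194 and miR-215; the miR-200 family; the miR-17 cluster with its paralogous clusters; the let-7, miR-30, miR-29, miR-34, miR-181 and miR-15 with miR-16 families; the miR-183 cluster; the miR-23, miR-27 and miR-24 clusters; miRNAs of the Hox loci, of the imprinted Dlk1-Dio3 locus and of stress and injury; and markers of endocrine, mesenchymal, leukocyte, red blood, endothelial, neural, hepatic with pancreatic acinar, and pluripotent cells. miR-34a-5p, miR-146a-5p and miR-155-5p each belong to more than 1 list. Intestinal epithelium expresses miR-146a-5p and members of the miR-100 and miR-125 families as well, so the mesenchymal and leukocyte lists are not exclusive to those cells. Each list is described by the median of its members detected on at least 1 of the arrays and by the percentile of that median among 10000 random lists of the same size, drawn for each member from the 50 miRNAs nearest in mean level. Random members were drawn independently, whereas members of a family or cluster need not move independently. A percentile is therefore a description and not a test.

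The miRNAs named below were chosen by a rule fixed before the data were examined: for each pair, the 8 largest differences each way among miRNAs detected on both arrays with a mean level above the median, the 4 largest bounds each way, and members of the lists. Among list members, those with the largest differences were picked as examples after their values were seen.

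Alternatives fixed before the data were examined were no background correction, normexp at an offset of 16, subtraction of the blank mean, scaling to the median of the miRNAs detected on all 4 arrays, scaling to the 75th percentile, cyclic loess, the deposited table of processed values, detection at 3 SD, no detection filter, and only miRNAs detected on all 4 arrays. A further 3 were made alternatives after values had been seen. They were normexp on the background column, which the design had named for the main fit, subtraction of the blank mean with scaling to the Spike Control spots, and the same with scaling to 8 epithelial miRNAs (miR-200a-3p, miR-200b-3p, miR-200c-3p, miR-141-3p, miR-429-3p, miR-192-5p, miR-194-5p and miR-215-5p). The median over repeat spots of a miRNA was not run, since each miRNA has 1 spot.

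Array number limits the precision. Over 5 control probes with 8 spots each, the SD of log2 intensity within an array averaged 0.0991 (range 0.0516 to 0.143). By that, 95% of differences between a pair of spots would lie within 0.275. This covers spot-to-spot error only, on control probes with means of 252 or more above the blank spots. It does not measure the spread between arrays, of a list median or of dim miRNAs, and serves below as a yardstick only. The procedure was tested on simulated arrays with the real blanks, brightness and spot noise, for villus against crypt over 1897 miRNAs with 200 of them changed. Of 50 changed 2-fold, 10.0% were called at least 2-fold, of 50 changed 4-fold 64.0%, and of 50 changed 8-fold 82.0%; the median measured folds were 1.47, 2.28 and 4.01. Of 1697 unchanged miRNAs, 2 were called. The measured folds were thus smaller than the simulated ones. All 4 simulated arrays shared 1 true profile, however, and the changed miRNAs were drawn only from probes above a set margin over the blank spots. The real arrays differed more widely, and there a fold can also be larger than under another scaling. For example, miR-215-5p on day 1 minus crypt had -2.53, but -0.90 with scaling to the median. Folds given below can thus understate or overstate a change. Names of neighbouring miRNA genes were taken from a RefSeq table of assembly GRCm38.p6, used for neighbour relations only. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.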

Results

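MicroRNA levels were measured in villus epithelium, crypt epithelium, and crypt-derived organoids on day 1 and day 5 of culture, with 1 array per group, to compare organoids with the epithelium they are meant to model. Of 1897 miRNA probes, 1506 were detected on the villus array, 1268 on the crypt array, 1555 on the day 1 array and 1359 on the day 5 array; 1148 were detected on all 4 and 1658 on at least 1. The Spike Control spots were 28928 above the blank spots on the villus array, 8523 on the crypt array, 16532 on the day 1 array and 8643 on the day 5 array, so the arrays differed in brightness by up to 3.39-fold. The villus, crypt and day 1 arrays lay on 1 slide and the day 5 array on another, so day 5 and its slide cannot be told apart.

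Quantile normalization holds the 4 distributions equal, and other scalings moved the median log2 difference of all miRNAs. With Spike Control scaling that median was 1.20 for villus minus crypt, 1.45 for day 1 minus crypt, 0.93 for day 5 minus crypt, -0.48 for day 5 minus day 1, 0.31 for day 1 minus villus and -0.20 for day 5 minus villus. With scaling to 8 epithelial miRNAs it was 1.35, 2.63, 1.72, -0.87, 1.34 and 0.44 in the same order. The deposited values gave 0.27, 0.44, 0.11, -0.28, 0.23 and -0.09, scaling to the 75th percentile -0.29, -0.33, -0.14, 0.20, 0.14 and 0.29, and scaling to the median -0.13, -0.17, -0.08, 0.10, 0.13 and 0.19. Below, "relative to all miRNAs" means after subtraction of these shifts. For miRNAs detected on both arrays, scalings with 1 factor per array and the same background step then give the same value. The median and the 75th percentile are therefore not separate tests there, nor are the Spike Controls and the epithelial miRNAs. The deposited values, also blank-subtracted with 1 factor per array, are nearly the same as these last and add no separate test either. Counts of scalings relative to all miRNAs below are to be read with this limit.

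Villus against crypt was taken as the differentiation axis of the epithelium in the animal. Whether RNA of other cell types adds to this difference stays open. The list medians of mesenchymal, leukocyte and endothelial cells were higher on the villus array. miR-145a-5p and miR-143-3p, which are made in smooth muscle and fibroblasts, were 22.8-fold and 18.9-fold higher (log2 difference 4.51 and 4.24), and miR-451a of red blood cells was 7.91-fold higher. On the crypt array, the miR-17 cluster, which is linked to proliferation, and the miR-200 family of epithelial cells were higher.

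Of 13 mesenchymal probes, 9 were at least 2-fold higher on the villus array and none lower, with a list median of 1.14 above all 10000 random lists; the probe shared by miR-199a-3p and miR-199b-3p had 2.25 and miR-125b-5p 1.76. Of these 13, 4 were detected on the villus array only, among them miR-1a-3p of muscle at least 2.90-fold and miR-100-5p at least 2.13-fold higher (the latter 0.96 with scaling to the median). Of 6 leukocyte probes, 3 were at least 2-fold higher (median 1.12, percentile 99.96), including miR-142a-5p at 1.71 and miR-142a-3p at 1.39. The endothelial list had a median of 1.13 over 2 probes (percentile 99.1), with miR-126a-3p at 1.84, and the red blood cell list had 1 of 4 probes at least 2-fold higher (median 0.46, percentile 98.2). Under all 6 other scalings these 4 medians stayed above 0, but with the background column subtracted they were 0.37, 0.27, -0.28 and 0.09. Under that setting the miR-199 probe had -0.20, miR-125b-5p -0.47, miR-142a-5p -0.10 and miR-126a-3p -0.28. By contrast, miR-143-3p kept 4.73, miR-145a-5p 4.04 and miR-451a 1.58 there. The other largest differences up were miR-6538 (11.7-fold), miR-6402 (9.63-fold), miR-7077-5p (6.92-fold), miR-8110 (5.66-fold) and miR-6240 (5.53-fold). All 8 largest up stayed at least 2-fold higher under all 6 other scalings and with the background column subtracted.

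Of 14 probes of the miR-17 cluster and its paralogs, 11 were at least 2-fold lower on the villus than on the crypt array (median -1.34, below all 10000 random lists), with miR-17-5p at -1.99 and miR-20a-5p at -1.74. That median stayed below 0 under all 6 other scalings, but it was -0.22 with scaling to the median, -0.38 with the 75th percentile and -0.53 with the Spike Controls, where no probe was at least 2-fold lower. Relative to all miRNAs it was -0.08 with scaling to the median and to the 75th percentile, and with the background column subtracted -0.68. Of 9 miR-200 probes, 5 were at least 2-fold lower (median -1.25, percentile 0.085), with miR-141-3p at -1.65 and miR-200a-3p at -1.57, but the median was 0.00 with scaling to the median, and relative to all miRNAs it also turned positive with scaling to the 75th percentile; with the background column subtracted it was -0.06. miR-141-3p had 0.16 with scaling to the median, and miR-200a-3p had 0.00 with that scaling and 1.40 with the background column subtracted. Of the endocrine list, miR-7a-5p (-1.27) and miR-375-3p (-1.18) were lower (median -1.18, percentile 0.98), whereas with the background column subtracted they had 0.03 and 0.01. For miR-192, miR-194 and miR-215, abundant miRNAs of intestinal epithelium, 2 of 6 probes were at least 2-fold lower on the villus array (median -0.75, percentile 7.68), but the list median was above 0 with scaling to the median, to the 75th percentile, to the Spike Controls and to the epithelial miRNAs. Among its members, miR-192-5p had -1.38, miR-215-5p -0.73 and miR-194-5p -0.62, but 0.49, 0.94 and 0.72 with scaling to the median. No let-7, miR-30 or miR-29 probe differed by 2-fold, with medians of -0.67, -0.28 and -0.31, and each of these medians was above 0 under the same 4 scalings. Relative to all miRNAs, these 3 medians and that of miR-192, miR-194 and miR-215 were above 0 only with scaling to the median and to the 75th percentile. Among scalings with 1 factor per array, that sign went with the background step, as set out above. Subtraction of the background column gave a let-7 median of 0.49 and a miR-29 median of 0.78. The largest differences down among single miRNAs were miR-6366 (6.75-fold), miR-1983 (6.37-fold), miR-375-5p (5.26-fold), miR-6412 (5.18-fold), miR-3084-3p (4.23-fold), miR-125a-3p (4.04-fold) and miR-7000-3p (4.01-fold). Of the 8 largest down, 2 stayed at least 2-fold lower with scaling to the median (miR-6412 had -0.38), 3 with the 75th percentile, 5 with Spike Control, 4 with epithelial scaling and all 8 with the background column subtracted.

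In all, 60 miRNAs were at least 2-fold higher and 52 lower on the villus array, of 1563 detected on either, and the SD of log2 differences was 0.61 over 1211 detected on both. Of these calls 53.6% were higher. The counts of higher and lower calls were 175 and 7 with scaling to the median, 892 and 35 with Spike Control scaling, 976 and 22 with scaling to the epithelial miRNAs, and 180 and 282 with the blank mean subtracted.

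**Figure D1:**
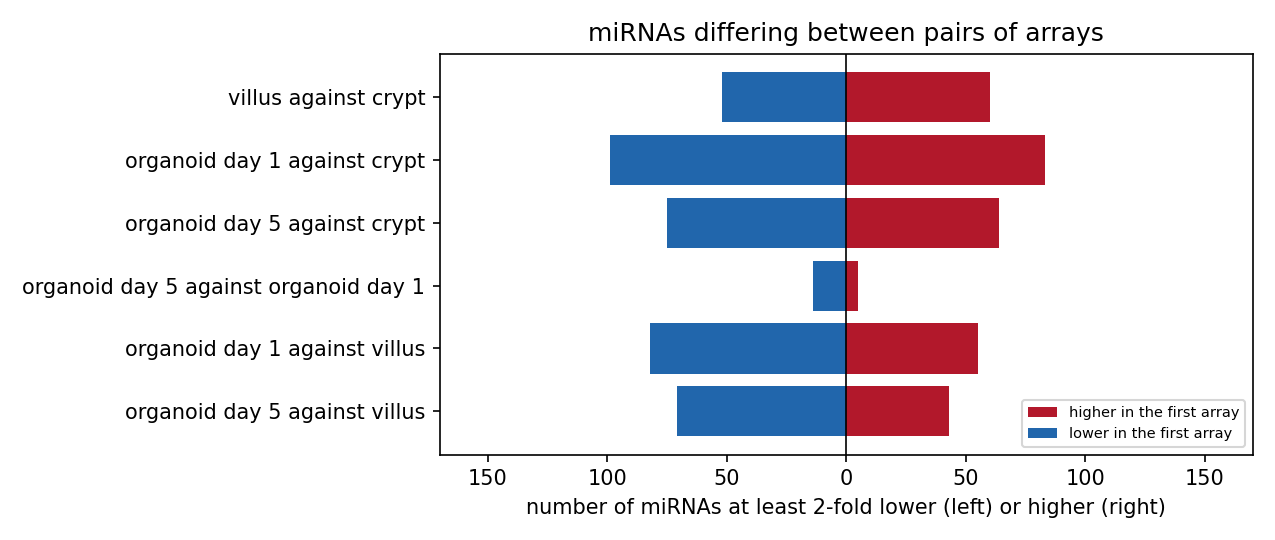
Bars give, for each pair of arrays, the number of miRNAs at least 2-fold lower (left, blue) or higher (right, red) on the first array, with 1 array per group and quantile normalization. The day 5 against day 1 pair had 5 higher and 14 lower, and day 1 against crypt had 83 and 99. The split into higher and lower changed with the scaling.

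Day 1 organoids against crypts compare early cultures with the tissue they were grown from. On the day 1 array, the list medians of intestinal and epithelial miRNAs and of the let-7, miR-30 and miR-29 families were lower than on the crypt array, though most of them were above 0 with scaling to the epithelial miRNAs. Among the largest differences down were miR-26a-5p (6.54-fold), miR-6412 (6.07-fold), miR-215-5p (5.77-fold), miR-192-5p (5.56-fold), let-7f-5p (5.52-fold), miR-17-5p (5.43-fold), miR-141-3p (5.34-fold) and miR-194-5p (5.03-fold). With scaling to the epithelial miRNAs, miR-6412 had 0.08, miR-215-5p 0.14, miR-192-5p 0.05 and miR-17-5p 0.02. The largest differences up were miR-6931-5p (28.7-fold), miR-711 (13.9-fold), miR-6769b-5p (13.1-fold), miR-7036a-5p (11.8-fold), miR-6937-5p (7.93-fold), miR-8099 (7.23-fold), miR-3473b (7.20-fold) and miR-3473e (7.11-fold). Of the 8 largest down, 4 stayed at least 2-fold lower with scaling to the median and none with epithelial scaling. The 8 largest up stayed at least 2-fold higher under all 6 other scalings, and 7 did with the background column subtracted, where miR-7036a-5p had 0.63 and miR-6769b-5p 1.72.

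Of 9 let-7 probes, which mark differentiated cells, all 9 were at least 2-fold lower (median -1.96, percentile 0.55), as were 5 of 6 probes of miR-192, miR-194 and miR-215 (median -1.78, percentile 0.56), 5 of 7 miR-30 probes (median -1.54, percentile 0.77) and all 3 miR-29 probes (median -1.98, percentile 1.48). let-7a-5p had -2.25, miR-30b-5p -2.23 and miR-29b-3p -2.23. The miR-17 cluster with its paralogs had 12 of 14 probes at least 2-fold lower (median -1.80, below all 10000 random lists; miR-20a-5p -2.29), and the miR-200 family 5 of 9 (median -2.14, percentile 0.025; miR-429-3p -2.33). These 6 medians stayed below 0 under 5 of the 6 other scalings, but with scaling to the epithelial miRNAs they were 0.25 for let-7, 0.43 for miR-192, miR-194 and miR-215, 0.21 for miR-30, -0.02 for miR-29, 0.00 for the miR-17 cluster and 0.33 for miR-200. That scaling is set on members of the miR-192 and miR-200 lists. Relative to all miRNAs, the 6 medians were below 0 under all 6 other scalings, between -0.52 and -2.65. With the background column subtracted, the medians were -1.14 for let-7, -1.01 for miR-192, miR-194 and miR-215, -0.43 for miR-30, -0.54 for miR-29, -0.92 for the miR-17 cluster and -0.48 for miR-200. By the same setting let-7f-5p and let-7a-5p had 1.25 and 1.19.

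Other lists lay lower on the day 1 array as well, again except with scaling to the epithelial miRNAs. The miR-23, miR-27 and miR-24 clusters had 3 of 6 probes at least 2-fold lower (median -1.18, percentile 20.5; miR-27b-3p -1.62), and the endocrine list 2 of 3 (median -1.29, percentile 2.38; miR-375-3p -1.40). With that scaling the medians were 1.10 and 0.38. In the stress and injury list, 4 of 12 detected probes were at least 2-fold lower (median -0.74, percentile 0.01), with miR-21a-5p at -1.30 and miR-31-5p at -1.06, while miR-210-3p, a hypoxia-induced miRNA, had 0.76; the list median was above 0 with Spike Control and with epithelial scaling. Of 10 detected mesenchymal probes, 2 were at least 2-fold lower, miR-143-3p (-1.63) and miR-145a-5p (-1.25), with a list median of -0.23 (percentile 2.36) that was above 0 under the same 2 scalings. With the background column subtracted, the stress and injury median was -0.05, the mesenchymal median 0.01 and miR-31-5p 2.46. miR-21a-5p had 0.16 with scaling to the median, 0.04 with Spike Control and 1.22 with epithelial scaling, which gave miR-31-5p 1.11. In all, 83 miRNAs were at least 2-fold higher and 99 lower of 1597 detected on either array, with an SD of 0.76 over 1226 detected on both. Of these calls 45.6% were higher. The direction of a call differed with the number in the miRNA's name. Of 754 miRNAs numbered from 1000 and detected on both arrays, 67 were higher and 21 lower. Of 363 numbered below 500, 9 were higher and 74 lower. The cause was not tested. The counts of higher and lower calls were 139 and 24 with scaling to the median, 122 and 46 with the 75th percentile, 59 and 108 with cyclic loess, 333 and 217 in the deposited values, 1022 and 76 with Spike Control and 1373 and 4 with epithelial scaling. Among miRNAs detected only on the day 1 array, the largest bounds were at least 1.97-fold for miR-125b-1-3p and 1.63-fold for miR-1912-5p; among those only on the crypt array, at least 1.81-fold for miR-7037-5p and 1.40-fold for miR-101a-3p.

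Day 5 organoids against crypts make the same comparison later in culture. miR-210-3p was 4.63-fold higher on the day 5 array. Its crypt intensity of 76.0 lay near the detection limit of 69.5, so the size is uncertain. The log2 difference was 2.21, but 1.76 with cyclic loess and 5.66 with epithelial scaling. The other largest differences up were miR-711 (10.5-fold), miR-6769b-5p (6.25-fold), miR-8119 (5.85-fold), miR-7036a-5p and miR-6937-5p (both 5.67-fold), miR-3473e (4.84-fold) and miR-6931-5p (4.68-fold). The largest differences down were in miR-215-5p (5.13-fold), miR-26a-5p (4.98-fold), miR-141-3p (4.26-fold), miR-30b-5p (3.70-fold), miR-148a-3p (3.67-fold), let-7f-5p (3.59-fold), let-7a-5p and miR-200c-3p (both 3.48-fold). Of the 8 largest down, 5 stayed at least 2-fold lower with scaling to the median, 5 with the 75th percentile, 4 with Spike Control, none with epithelial scaling and 5 with the background column subtracted.

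At least 2-fold lower were 8 of 9 let-7 probes (median -1.67, below all 10000 random lists), 5 of 6 probes of miR-192, miR-194 and miR-215 (median -1.62, percentile 0.02), 5 of 7 miR-30 probes (median -1.25, percentile 0.49), 3 of 3 miR-29 probes (median -1.48, percentile 2.54), 5 of 9 miR-200 probes (median -1.37, percentile 0.21) and 9 of 14 probes of the miR-17 cluster and its paralogs (median -1.18, percentile 0.38). miR-194-5p had -1.68, miR-192-5p -1.67, miR-29a-3p -1.65 and miR-19b-3p -1.51. Under 5 of the 6 other scalings all 6 medians were below 0, but with scaling to the epithelial miRNAs they were 0.23 for let-7, 0.02 for miR-30, -0.11 for miR-29, 0.32 for miR-200 and 0.39 for the miR-17 cluster, while the median of miR-192, miR-194 and miR-215 stayed below 0. With the background column subtracted, the medians shrank to -0.15 for let-7, -0.18 for miR-29, -0.45 for miR-30, -0.0049 for miR-200, -0.53 for the miR-17 cluster and -0.95 for miR-192, miR-194 and miR-215. Here let-7f-5p, let-7a-5p and miR-29a-3p had 2.80, 1.43 and 0.74. Relative to all miRNAs, the let-7 median lay between -0.61 and -1.48 and the miR-30 median between -0.70 and -1.69 under the 6 scalings.

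Of 12 detected stress and injury probes, 3 were at least 2-fold lower, including miR-31-5p (-1.33) and miR-21a-5p (-1.04), and 1 higher, miR-210-3p; the list median of -0.41 (percentile 0.31) was above 0 with Spike Control and with epithelial scaling. Those scalings gave miR-21a-5p 0.06 and 0.85, and miR-31-5p had 0.30 with epithelial scaling and 1.90 with the background column subtracted. miR-27b-3p (-1.23) of the miR-23, miR-27 and miR-24 clusters (median -0.50, percentile 22.1) and miR-375-3p (-1.06) of the endocrine list (median -0.39, percentile 12.7) were lower too, and both medians were above 0 with epithelial scaling, the first also with Spike Control scaling, and the endocrine median and miR-375-3p both had 0.25 with the background column subtracted. On the mesenchymal list, miR-143-3p and miR-145a-5p were detected on the crypt array only, at least 3.27-fold and 2.45-fold lower on day 5, and of 9 detected probes no other passed 2-fold (median -0.25, percentile 1.94, above 0 with Spike Control and epithelial scaling). miR-146a-5p and miR-152-3p, also detected on the crypt array only, were at least 2.22-fold and 2.05-fold lower. These 4 bounds fell short of 2-fold with scaling to the median (-0.996, -0.76, -0.69 and -0.61) and with the background column subtracted (-0.23, -0.61, -0.58 and -0.42). In all, 64 miRNAs were at least 2-fold higher and 75 lower of 1464 detected on either array, with an SD of 0.61 over 1163 detected on both. Of these calls 46.0% were higher. Of 733 miRNAs numbered from 1000 and detected on both arrays, 50 were higher and 14 lower. Of 333 numbered below 500, 10 were higher and 54 lower. The counts of higher and lower calls were 78 and 9 with scaling to the median, 77 and 15 with the 75th percentile, 634 and 55 with Spike Control and 1075 and 10 with epithelial scaling.

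**Figure D2:**
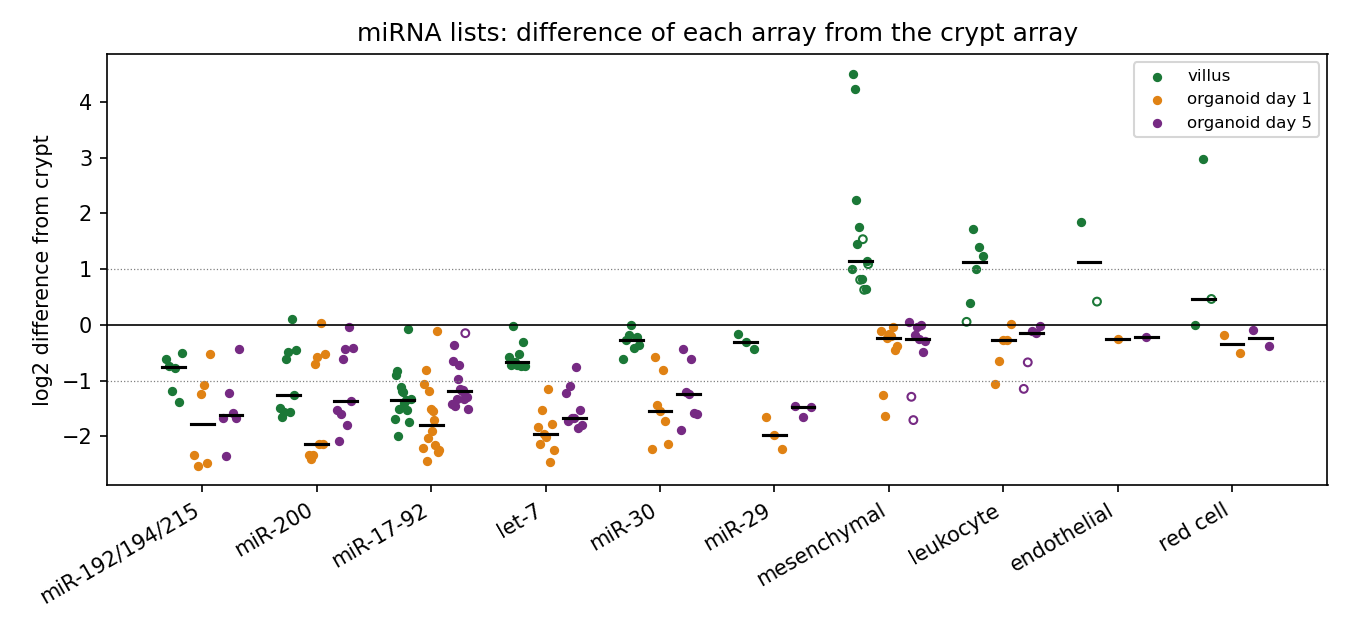
Points give the log2 difference from the crypt array of each list member on the villus (green), day 1 (orange) and day 5 (purple) arrays under quantile normalization, open points are lower bounds for miRNAs detected on 1 of the arrays, black lines are list medians and dotted lines mark 2-fold. The mesenchymal median was 1.14 on the villus array and -0.23 and -0.25 on the organoid arrays, and the let-7 medians were -0.67, -1.96 and -1.67; all 3 let-7 medians were above 0 with scaling to the epithelial miRNAs and the villus let-7 median also with scaling to the median, to the 75th percentile and to the Spike Controls. Both organoid mesenchymal medians were above 0 with Spike Control and epithelial scaling.

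Day 5 against day 1 follows the organoids during culture, and this pair lay closest of the 6. miR-210-3p was 2.73-fold higher on day 5, followed by miR-690 (2.44-fold), miR-6412 (2.24-fold), miR-1902 (2.09-fold) and miR-1949 (2.04-fold), which completes the 5 miRNAs at least 2-fold higher; with the background column subtracted miR-6412 had -1.33. Lower on day 5 were miR-6931-5p (6.12-fold), miR-5099 (2.66-fold), miR-7224-5p (2.58-fold), miR-5129-5p (2.47-fold), miR-7023-5p (2.41-fold), miR-6941-5p (2.31-fold), miR-8113 (2.27-fold) and miR-491-5p (2.26-fold), among 14 in all of 1568 detected on either array. Of the 5 higher, 1 stayed at least 2-fold higher with scaling to the median, to the 75th percentile or to the epithelial miRNAs, 2 with Spike Control scaling and 3 with the background column subtracted, which kept 5 of the 8 largest down.

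The miR-17 cluster and its paralogs had a median of 0.71 on day 5 relative to day 1, above all 10000 random lists and above 0 under all 6 other scalings, with miR-20a-5p at 0.99 and miR-17-5p at 0.98, although none of its 14 probes reached 2-fold. Subtraction of the background column gave a median of 0.48, 1.62 for miR-17-5p and -0.56 for miR-20a-5p. Likewise without a probe at 2-fold, the endocrine list had 0.34 (percentile 98.8; miR-7a-5p 0.90), above 0 under all 6 other scalings. The medians of miR-200 (0.33, percentile 99.6; miR-429-3p 0.80), let-7 (0.42, percentile 97.8; let-7f-5p 0.62), miR-30 (0.23, percentile 95.3), miR-29 (0.33, percentile 89.0; miR-29b-3p 0.75) and the miR-23, miR-27 and miR-24 clusters (0.29, percentile 94.1; miR-24-3p 0.74) were above 0 under 5 of the 6 other scalings and below 0 with scaling to the epithelial miRNAs. Relative to all miRNAs, the let-7, miR-30 and miR-29 medians and that of the miR-23, miR-27 and miR-24 clusters (-0.085) were below 0 with scaling to the median and to the 75th percentile instead. Among scalings with 1 factor per array, this again went with the background step. The miR-30 median was -0.02 and that of the miR-23, miR-27 and miR-24 clusters 0.0090 with the background column subtracted, and miR-429-3p had -0.11. For miR-192, miR-194 and miR-215 the median was 0.14 (percentile 76.1; miR-192-5p 0.81), below 0 under 4 other scalings, which were the median, the 75th percentile, the Spike Controls and the epithelial miRNAs. The mesenchymal, leukocyte, red blood cell and endothelial medians lay between -0.02 and 0.11 with no probe at 2-fold, and each was of the other sign under at least 2 of the 6 scalings. The stress and injury median was 0.16 (percentile 99.1), below 0 only with epithelial scaling among the scalings. The SD of log2 differences was 0.28 over 1346 miRNAs, the lowest of the 6 pairs. Of the 19 calls 26.3% were higher. The counts of higher and lower calls were 1 and 33 with scaling to the median, 1 and 29 with the 75th percentile, 15 and 301 with Spike Control and 5 and 675 with epithelial scaling. They were 102 and 64 with the blank mean subtracted, and 26 each with the background column subtracted.

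Day 1 organoids against villus compare cultures with differentiated epithelium. Several mesenchymal and blood cell miRNAs of the villus array were far lower on the day 1 array: miR-143-3p was 58.4-fold and miR-145a-5p 54.3-fold lower, miR-451a 11.2-fold, and miR-1a-3p, detected on the villus array only, at least 3.15-fold. The miR-29, miR-30 and let-7 families were lower as well. Higher on day 1 were miR-8099 (12.6-fold), miR-7036a-5p (11.5-fold), miR-6931-5p (9.93-fold), miR-8119 (8.52-fold), miR-6769b-5p (8.33-fold), miR-6937-5p (6.21-fold), miR-128-2-5p (6.10-fold) and miR-5099 (5.86-fold). Subtraction of the background column gave 0.72 for miR-7036a-5p and a bound of -0.03 for miR-1a-3p.

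Of 13 mesenchymal probes, 10 were at least 2-fold lower on the day 1 array (median -1.51), as were 5 of 6 leukocyte probes (median -1.37), both below all 10000 random lists, 1 of 2 endothelial probes (median -1.32, percentile 0.06) and 1 of 4 red blood cell probes (median -0.38, percentile 1.59). The shared miR-199a-3p and miR-199b-3p probe had -2.48, miR-142a-5p -2.37, miR-126a-3p -2.09, miR-125b-5p -1.96 and miR-146a-5p -1.47. At least 2-fold lower were also 8 of 9 let-7 probes (median -1.43, percentile 0.52; let-7f-5p -1.73), 5 of 7 miR-30 probes (median -1.49, percentile 0.10; miR-30c-5p -1.78), 3 of 3 miR-29 probes (median -1.67, percentile 0.98; miR-29b-3p -1.80) and 5 of 7 probes of the miR-23, miR-27 and miR-24 clusters (median -1.56, percentile 0.18; miR-24-3p -1.79). All 8 of these medians were below 0 under all 6 other scalings. With the background column subtracted they were -0.25 for the mesenchymal, -0.39 for the leukocyte, 0.31 for the endothelial and -0.12 for the red blood cell list, -1.12 for let-7, -0.26 for miR-30, -1.32 for miR-29 and -0.998 for the miR-23, miR-27 and miR-24 clusters. Under that setting the miR-199 probe had 0.28, miR-125b-5p 0.37, miR-126a-3p 0.31 and miR-30c-5p 0.63. For miR-192, miR-194 and miR-215, 3 of 6 probes were at least 2-fold lower (median -0.70, percentile 4.95; miR-215-5p -1.80, miR-194-5p -1.71), a median that among the scalings was above 0 only with the epithelial one, which is set on these miRNAs.

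No probe of the miR-200 family or of the miR-17 cluster and its paralogs differed by 2-fold between day 1 and villus; their medians were -0.58 (percentile 0.77) and -0.41 (percentile 2.02), and both were above 0 with epithelial scaling. The endocrine median was -0.14 (percentile 16.6), also above 0 with that scaling, and the stress and injury median -0.12 (percentile 2.82), likewise, with miR-210-3p at 0.90. The remaining largest differences down were miR-7077-5p (20.4-fold), miR-6538 (11.2-fold), miR-6402 (10.4-fold), miR-494-3p (6.45-fold) and miR-6999-5p (5.60-fold). In all, 55 miRNAs were at least 2-fold higher and 82 lower of 1632 detected on either array, with an SD of 0.65 over 1429 detected on both. Of these calls 40.1% were higher. The counts of higher and lower calls were 53 and 110 with scaling to the median, 199 and 188 in the deposited values, 273 and 202 with Spike Control and 1053 and 57 with epithelial scaling.

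Day 5 organoids against villus showed several of the same mesenchymal and blood cell miRNAs lower. miR-143-3p and miR-145a-5p were not detected on the day 5 array and were at least 61.7-fold and 55.7-fold lower than on the villus array, miR-142a-5p at least 5.23-fold and miR-1a-3p at least 2.98-fold, and miR-451a was 10.2-fold lower; with the background column subtracted the bounds for miR-142a-5p and miR-1a-3p were -0.26 and -0.05. Higher on day 5 were miR-8119 (10.5-fold), miR-8099 (6.10-fold), miR-6366 (5.53-fold), miR-7036a-5p (5.50-fold), miR-7047-5p (5.34-fold), miR-210-3p and miR-6244 (both 5.09-fold) and miR-6937-5p (4.44-fold).

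At least 2-fold lower on day 5 were 9 of 13 mesenchymal probes (median -1.44) and 5 of 6 leukocyte probes (median -1.39), both below all 10000 random lists, 1 of 2 endothelial probes (median -1.26, percentile 0.025) and 1 of 4 red blood cell probes (median -0.50, percentile 3.89), with miR-126a-3p at -2.06 and miR-125b-5p at -2.01. miR-146a-5p, detected on the villus array only, was at least 2.92-fold lower. The let-7 family had 6 of 9 probes at least 2-fold lower (median -1.02, percentile 1.24; let-7b-5p -1.23), miR-30 5 of 7 (median -1.24, percentile 0.16; miR-30e-5p -1.36), miR-29 3 of 3 (median -1.29, percentile 4.60; miR-29a-3p -1.34) and the miR-23, miR-27 and miR-24 clusters 4 of 7 (median -1.05, percentile 0.60; miR-23b-3p -1.45). These 8 medians were below 0 under all 6 other scalings. With the background column subtracted the endothelial median was 0.02, the mesenchymal -0.27, the leukocyte -0.48 and the red blood cell median -0.13, and those of let-7, miR-30, miR-29 and the miR-23, miR-27 and miR-24 clusters were -0.87, -0.34, -0.96 and -0.78. Under that setting the miR-199 probe had 0.18, miR-125b-5p 0.33 and miR-126a-3p 0.15. For miR-192, miR-194 and miR-215, 2 of 6 probes were at least 2-fold lower, miR-215-5p (-1.63) and miR-194-5p (-1.06), with a median of -0.54 (percentile 3.68) that was below 0 under all 6 other scalings.

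The miR-200 median was -0.03 (percentile 21.5) with no probe at 2-fold, above 0 with epithelial scaling and with the background column subtracted (0.11), and that of the miR-17 cluster and its paralogs 0.20 (percentile 75.5), below 0 with scaling to the median and to the 75th percentile. The endocrine median was 0.13 (percentile 65.9), and that of stress and injury -0.05 (percentile 5.75), above 0 under 4 of the 6 other scalings. The other largest differences down were miR-7077-5p (20.2-fold), miR-6538 (12.6-fold), miR-6402 (11.6-fold), miR-6999-5p (5.97-fold), the probe shared by miR-199a-3p and miR-199b-3p (5.36-fold), miR-3154 (4.80-fold) and miR-494-3p (4.69-fold). In all, 43 miRNAs were at least 2-fold higher and 71 lower of 1539 detected on either array, with an SD of 0.56 over 1326 detected on both. Of these calls 37.7% were higher. The counts of higher and lower calls were 20 and 119 with scaling to the median, 27 and 106 with the 75th percentile, 103 and 297 with Spike Control and 303 and 130 with epithelial scaling. They were 177 and 181 with the blank mean subtracted and 35 and 34 with the background column subtracted.

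The change from day 1 to day 5 was set against the villus minus crypt difference to ask whether organoids in culture moved along the tissue axis. That difference may also hold RNA of other cell types, which stays open. Across the 1148 miRNAs detected on all 4 arrays, Pearson's r was -0.39 and Spearman's rho -0.36, and 38.1% of miRNAs had the same sign in both. miR-17-5p and miR-20a-5p, lower on villus than on crypt, lay higher on day 5 than on day 1, though miR-20a-5p lay lower on day 5 (-0.56) with the background column subtracted. miRNAs are not independent replicates, and r was 0.23 with the background column subtracted.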

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

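All tests in this part, and as alternatives the settings with the background column, the Spike Controls and the 8 epithelial miRNAs, were chosen after the results were seen.

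Of 22 control probes named S-Probe with 1 spot each, which no comparison uses, 14 were above the detection limit on all 4 arrays. S-Probe1014 reached 79.0% of the Spike Control signal on the villus array, against 33.4% on the crypt, 27.9% on the day 1 and 26.4% on the day 5 array.

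The medians of the mesenchymal, leukocyte, endothelial and red blood cell lists were higher on the villus than on the crypt array, with 9 of 13, 3 of 6, 1 of 2 and 1 of 4 probes at least 2-fold higher. Scaling is argued against for the first 3 lists, whose lowest median under the 6 other scalings was 1.15; for red blood cells it stays open, as the lowest median was 0.21, within the 95% range between repeat spots. The background correction stays open for all 4, since with the background column subtracted the medians were 0.37, 0.27, -0.28 and 0.09 in the same order. Single members went both ways there. miR-143-3p, miR-145a-5p and miR-451a, among the 8 largest differences up, kept 4.73, 4.04 and 1.58. The miR-199 probe, miR-125b-5p, miR-142a-5p and miR-126a-3p were below 0. That column followed the brightness of its own spot, however, so its subtraction can also remove signal. The other background settings kept all 4 medians above 0. They were 1.03, 0.94, 0.96 and 0.36 without correction, 1.72, 1.63, 1.62 and 0.82 at an offset of 16, and 3.02, 2.56, 2.83 and 2.16 with the blank mean subtracted. RNA of other cell types stays open too. With Spike Control scaling the lowest of the 4 lists lay 2.58 log2 units above the 8 epithelial miRNAs, and the neural list 1.23. All miRNAs had a median of 1.20 under that scaling, against -0.22 for the 8, so the neural list cannot serve as a control there. Relative to all miRNAs, the neural list had -0.19 and the hepatic with pancreatic list -1.05. The 4 lists had 3.06, 2.71, 2.92 and 1.17 in the same order as above. They were picked for being higher on villus, so these values do not settle it. A difference between villus and crypt epithelium itself was not tested and stays open.

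The medians of the miR-192 with miR-194 and miR-215, let-7, miR-30 and miR-29 lists were lower on both organoid arrays than on the crypt array, though those of let-7 and miR-30 were above 0 on both with scaling to the epithelial miRNAs. A shift of miRNAs numbered below 500 in general stays open: with Spike Control scaling, those outside the lists had a median of 0.65 on day 1 minus crypt against 1.64 for those numbered from 1000, and the smaller of the gaps, on day 5, was -0.64. The list members lay lower still. Relative to matched low-numbered miRNAs outside the lists, 10 for each of the 25 members, they had -0.77 on day 1 and -0.72 on day 5. The lists were picked for being lower, however, which by itself can give such a gap. The values thus cannot tell whether such a shift covers the fall in part or in full. Quantile normalization is argued against for the fall relative to all miRNAs, as the highest of the 4 list medians with 1 factor per array in its place was -0.52, but scaling stays open for the level on the array: scaling to the epithelial miRNAs, which is set on miRNAs that fell and puts the median of all miRNAs 2.63 above crypt on day 1, gave 0.21 for the 19 let-7, miR-30 and miR-29 members. The background correction stays open, as with the background column subtracted the highest of the 4 medians was -0.15, for let-7 on day 5. That column followed the brightness of its own spot, however. Over the 25 members, the medians on day 1 and day 5 were -1.73 and -1.46 without background correction. They were -2.07 and -1.69 at an offset of 16, and -2.33 and -1.81 with the blank mean subtracted. An effect of culture was not tested apart from these and stays open.

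The day 5 minus day 1 differences ran against the villus minus crypt differences across miRNAs. A lift of dim spots on the brighter arrays is argued against, because among the 287 miRNAs with the highest levels r was -0.45. The background correction stays open, since r was 0.23 with the background column subtracted. That column followed the brightness of its own spot, however, and r stayed below 0 under the other background settings. Other effects of brightness stay open too, as the villus and day 1 arrays were the brighter ones, so that each of the differences sets a brighter against a dimmer array. Taken as brighter minus dimmer, villus minus crypt with day 1 minus day 5 had r 0.39. The other such pairing, villus minus day 5 with day 1 minus crypt, had r -0.41. It sets tissue minus organoid against organoid minus tissue, so a difference between organoids and tissue pulls r below 0 whatever brightness does. Villus minus day 1 with crypt minus day 5, tissue minus organoid in both, had r 0.63. The pairings thus do not settle it. A change of the organoids in culture stays open as well, and it cannot be separated from the slide of the day 5 array.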

How the results depend on the processing

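The settings with the background column, the Spike Controls and the 8 epithelial miRNAs were chosen as alternatives after the results were seen, though the design had named the first for the main fit. No paired analysis was possible because the groups share only replicate number 1, with 1 sample each. Leaving out an array in turn was not possible with 1 array per group, and the median over repeat spots was not run because each miRNA has 1 spot. Array signal limits what can be seen: the median miRNA intensity was 72.0 on the crypt array, with a detection limit of 69.5, and of 50 miRNAs simulated with a 2-fold change 5 were called. Among 19 main results, 147 values under alternatives stayed within 1.5 times the count or SD, or within the 95% interval of r, 99 moved beyond that, and 1 changed sign. Of the values of lists and single miRNAs, 2383 stayed within the 95% range between repeat spots, 1926 moved beyond it, and 75 of those at least 2-fold changed sign. All 19 main results stayed within these limits without background correction, with detection at 3 SD, with no detection filter and with only miRNAs detected on all 4 arrays. Below, each setting is given with the values that moved, as miRNAs at least 2-fold higher or lower on the first array, the SD of log2 differences, and r of the day 5 minus day 1 with the villus minus crypt differences. List medians and single miRNAs are called reversed below only where they were at least 2-fold in the main setting. Smaller ones that changed sign are not listed here. For all of them the cause was not tested.

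With normexp at an offset of 16, villus against crypt had 79 lower, and day 5 against day 1 had 11 higher. Day 5 against villus had 66 higher. With the blank mean subtracted, villus against crypt had 180 higher, 282 lower and an SD of 1.08, and day 1 against crypt had 244 higher, 327 lower and an SD of 1.29. Against crypt, day 5 had 193 higher, 241 lower and an SD of 1.00, and day 5 against day 1 had 102 higher, 64 lower and an SD of 0.61. Against villus, day 1 had 213 higher, 248 lower and an SD of 1.20, and day 5 against villus had 177 higher, 181 lower and an SD of 1.02. Here r was -0.30. With scaling to the median of the miRNAs detected on all 4 arrays, villus against crypt had 175 higher and 7 lower, and day 1 against crypt had 139 higher and 24 lower. Day 5 against crypt had 9 lower, and day 5 against day 1 had 1 higher and 33 lower. Day 5 against villus had 20 higher and 119 lower. Here r was -0.55. For villus against crypt, the list median of reversed direction was 0.0030 for miR-200. Villus against crypt gave reversed values for miR-141-3p 0.16, miR-200a-3p 0.0030 and miR-192-5p 0.49. Day 1 against crypt gave reversed values for miR-21a-5p 0.16. With scaling to the 75th percentile, villus against crypt had 142 higher and 110 lower, and day 1 against crypt had 46 lower. Against crypt, day 5 had 15 lower, and day 5 against day 1 had 1 higher and 29 lower. Day 5 against villus had 27 higher. Here r was -0.55. Villus against crypt gave reversed values for miR-192-5p 0.33. With cyclic loess, day 5 against crypt had 42 higher. Here r was -0.20. In the deposited processed values, villus against crypt had 222 higher, 143 lower and an SD of 1.07, and day 1 against crypt had 333 higher, 217 lower and an SD of 1.27. Against crypt, day 5 had 207 higher, 180 lower and an SD of 1.03, and day 5 against day 1 had 38 higher, 153 lower and an SD of 0.62. Against villus, day 1 had 199 higher, 188 lower and an SD of 1.17, and day 5 against villus had 105 higher, 207 lower and an SD of 1.04. Here r was -0.29.

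With Spike Control scaling, villus against crypt had 892 higher and an SD of 1.07, and day 1 against crypt had 1022 higher and an SD of 1.27. Day 5 against crypt had 634 higher and an SD of 1.03, and day 5 against day 1 had 15 higher, 301 lower and an SD of 0.62. Day 1 against villus had 273 higher, 202 lower and an SD of 1.17, and day 5 against villus had 103 higher, 297 lower and an SD of 1.04. Here r was -0.29. Day 1 against crypt gave reversed values for miR-21a-5p 0.036. Day 5 against crypt gave reversed values for miR-21a-5p 0.057. With scaling to the 8 epithelial miRNAs, villus against crypt had 976 higher, 22 lower and an SD of 1.07, and day 1 against crypt had 1373 higher, 4 lower and an SD of 1.27. Against crypt, day 5 had 1075 higher, 10 lower and an SD of 1.03, and day 5 against day 1 had 675 lower and an SD of 0.62. Against villus, day 1 had 1053 higher and an SD of 1.17, and day 5 against villus had 303 higher, 130 lower and an SD of 1.04. Here r was -0.29. For day 1 against crypt, list medians of reversed direction were 0.43 for miR-192, miR-194 and miR-215, 0.33 for miR-200, 0.0029 for the miR-17 cluster with its paralogs, 0.25 for let-7, 0.21 for miR-30, 0.84 for the miR-183 cluster, 1.10 for the miR-23, miR-27 and miR-24 clusters, 0.65 for miR-15 with miR-16 and 0.38 for endocrine cells. For day 5 against crypt, list medians of reversed direction were 0.32 for miR-200, 0.39 for the miR-17 cluster with its paralogs, 0.23 for let-7 and 0.024 for miR-30. Villus against crypt gave reversed values for miR-192-5p 0.092. Against crypt, day 1 gave reversed values for miR-6412 0.082, miR-215-5p 0.14, miR-192-5p 0.048, miR-17-5p 0.021, let-7a-5p 0.21, miR-27b-3p 0.47, miR-375-3p 0.38, miR-21a-5p 1.22, miR-31-5p 1.11, miR-10a-5p 0.16, miR-96-5p 0.28 and miR-181a-5p 0.24. Against crypt, day 5 gave reversed values for let-7f-5p 0.082, miR-200c-3p 0.18, let-7a-5p 0.23, miR-192-5p 0.068, miR-19b-3p 0.38, miR-16-5p 0.12, miR-27b-3p 0.37, miR-375-3p 0.22, miR-21a-5p 0.85 and miR-31-5p 0.30.

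With normexp on the background column, as the design had called for, villus against crypt had 57 higher, 53 lower and an SD of 0.70, and day 1 against crypt had 58 higher, 61 lower and an SD of 0.61. Day 5 against crypt had 53 higher, 51 lower and an SD of 0.62, and day 5 against day 1 had 26 higher, 26 lower and an SD of 0.39. Day 1 against villus had 48 higher, 52 lower and an SD of 0.58, and day 5 against villus had 35 higher, 34 lower and an SD of 0.46. Here r was 0.23. These are all 19 main results, moved or not. For villus against crypt, list medians of reversed direction were 0.012 for endocrine cells and -0.28 for endothelial cells. For day 1 against villus, list medians of reversed direction were 0.15 for miR-15 with miR-16 and 0.31 for endothelial cells. For day 5 against villus, the list median of reversed direction was 0.019 for endothelial cells. Villus against crypt gave reversed values for miR-199a-3p with miR-199b-3p -0.20, miR-125b-5p -0.47, miR-142a-5p -0.10, miR-126a-3p -0.28, miR-200a-3p 1.40, miR-7a-5p 0.027 and miR-375-3p 0.012. Day 1 against crypt gave reversed values for let-7f-5p 1.25, let-7a-5p 1.19, miR-31-5p 2.46 and miR-10a-5p 0.18. Day 5 against crypt gave reversed values for let-7f-5p 2.80, let-7a-5p 1.43, miR-29a-3p 0.74, miR-375-3p 0.25 and miR-31-5p 1.90. Day 5 against day 1 gave reversed values for miR-6412 -1.33. Day 1 against villus gave reversed values for miR-199a-3p with miR-199b-3p 0.28, miR-125b-5p 0.37, miR-126a-3p 0.31, miR-30c-5p 0.63 and miR-195a-5p 0.19. Day 5 against villus gave reversed values for miR-199a-3p with miR-199b-3p 0.18, miR-125b-5p 0.33, miR-126a-3p 0.15 and miR-195a-5p 0.22.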

Other observations

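The tests of neighbouring genes in this part were chosen after the results were seen. Further lists lay lower on the organoid arrays. Of 7 probes of the miR-15 with miR-16 family, which restrains the cell cycle, 4 were at least 2-fold lower on day 1 than on crypt (median -1.22, percentile 0.090; miR-16-5p -2.27) and 3 on day 5 (median -0.74, percentile 0.25; miR-16-5p -1.64). Both medians were above 0 only with scaling to the epithelial miRNAs among the scalings, and they were -0.36 and -0.18 with the background column subtracted. Against villus, 4 were lower on day 1 (median -1.27, percentile 0.070; miR-195a-5p -1.75) and 2 on day 5 (median -0.89, percentile 0.365; miR-195a-5p -1.63), with both medians below 0 under all 6 other scalings, while with the background column subtracted they were 0.15 and -0.02 and miR-195a-5p had 0.19 and 0.22. miR-497a-5p, which shares a cluster with miR-195a, was 1.05 higher on villus than on crypt.

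Of 5 miRNAs of the Hox loci, 2 were at least 2-fold lower on day 1 than on crypt (median -0.79, percentile 0.055; miR-10a-5p -1.29), and none on day 5 (median -0.52, percentile 0.355); both medians were above 0 with epithelial scaling, and with the background column subtracted they were -0.0043 and 0.02. Under that setting miR-10a-5p had 0.18 on day 1 relative to crypt. miR-10a-5p was also lower than on villus, with -1.63 on day 1 and -1.18 on day 5. Of 4 miR-181 probes, 1 was at least 2-fold lower on day 1 than on crypt, miR-181a-5p at -1.01 (median -0.61, percentile 0.050, above 0 with epithelial scaling and -0.02 with the background column subtracted). In the miR-183 cluster of epithelial and sensory cells, 2 of 3 probes were at least 2-fold lower on day 1 than on crypt (median -1.12, percentile 1.99; miR-96-5p -1.34), above 0 with epithelial scaling and -0.07 with the background column subtracted. On day 5 relative to day 1 the cluster's median was 0.59 (percentile 99.9; miR-96-5p 0.75), above 0 under all 6 other scalings but -0.14 with the background column subtracted, with no probe at 2-fold.

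The leukocyte list had 1 of 5 detected probes at least 2-fold lower on day 1 than on crypt (median -0.28, percentile 4.385) and 1 of 5 on day 5 (median -0.14, percentile 10.4). No red blood cell or endothelial probe differed by 2-fold between either organoid array and crypt, with medians of -0.34 and -0.26 on day 1 and -0.24 and -0.22 on day 5. All 6 of these medians were above 0 with epithelial scaling, and the 2 of red blood cells also with Spike Control scaling. With the background column subtracted, both red blood cell medians were above 0 too, as was the endothelial one on day 1.

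No miR-34, neural or hepatic with pancreatic probe differed by 2-fold in any of the 6 pairs. For day 1 against crypt their medians were -0.13, -0.20 and -0.09 (percentiles 18.7, 5.87 and 27.5), each above 0 with epithelial scaling, the first and the last of them also with Spike Control scaling and the last also with cyclic loess. Of the imprinted Dlk1-Dio3 locus, miR-487b-3p alone was at least 2-fold lower on villus than on crypt (-1.68), in a list of 18 detected probes (median -0.01, percentile 55.6; above 0 with cyclic loess, Spike Control and epithelial scaling). Of the pluripotency list, miR-290a-5p was 1.18 higher on day 5 than on villus, while the median was 0.07 over 6 detected probes (percentile 68.0; below 0 with Spike Control scaling).

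A hypothesis was that miRNAs from neighbouring genes move alike because of shared transcripts. Over 412 pairs of miRNAs whose genes lie within 10 kb, among 1040 miRNAs, the median gap between the differences of a pair was compared with 1000 random draws matched on level. The number of draws with a gap as small was 0 for day 1 against crypt and 0 for day 5 against crypt, 341 for villus against crypt, 874 for day 5 against day 1, 237 for day 1 against villus and 158 for day 5 against villus. With at most 50 such draws in 2 of 6 comparisons, the test leaves shared transcripts open. These 2 share the crypt array, so they are not independent. They also differed most by name number, by 0.26 on day 1 and 0.17 on day 5. That is the median of miRNAs numbered from 1000 minus that of those below 500. The draws were matched on level and not on name number, so the test cannot set this apart.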
